A study of Rattus norvegicus and Mus musculus and Homo sapiens with 29 samples.

How the data were processed

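The deposited matrices hold UMI counts per gene and spot that the authors made with Space Ranger 1.2.1, per the submitters' processing notes, for spots that the software placed under tissue, and no normalisation was applied to them. The notes name the builds mm10 for mouse and GRCh38 for human; the rat build is not given in the sources used here. Some mouse libraries merged sequencing runs, and 2 libraries held 2 pieces of tissue. All values were whole numbers with totals that differed between libraries, and each matrix matched its list of spot barcodes and its table of spot positions. Every one of the 29 libraries was mapped to a group by its title. The titles and file names of experiment 4 disagree on which rat libraries had a coverslip, and the titles were followed. Tissue images and the image scale factors were not used here.

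UMIs were summed over all tissue spots of a library, and over the libraries of a mouse where it had more than 1, so that the animal was the unit for mouse tumours. Rat labels name no animals, so the library was the unit there. For the comparison of edge and core, distance was counted in steps on the spot lattice to the nearest array position not under tissue, without counting the array border, and UMIs were summed over spots at 1 to 2 steps and over spots at 6 or more steps in each mouse. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). The designs were line at day 16 (3 mice against 3), day with line as a term (8 mice), line by day, edge against core with the mouse as a block (8 mice), position by line with the mouse as a block, FFPE against fresh frozen of experiments 1 and 2 (3 libraries against 8), coverslip against none in experiment 4 (2 against 2) and experiment 2 against experiment 1 (4 against 4). Experiment 4 was left out of the FFPE comparison because of the conflict over the coverslip. CPM are counts scaled to a library total of 1000000, with TMM factors for single genes unless stated and without them for lists, SD is between mice or libraries, and SE is that of the fitted log2 difference.

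Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The percentage of spots with more epithelium than smooth-muscle UMIs and the number of tissue spots were compared between rat groups as measures added later. Named genes were members of the fixed lists, and in each direction the 12 genes with the largest change among those past the threshold with a mean of at least 30 CPM and groups that did not overlap, gene models without a symbol being left out. A further gene named by this rule in the comparison of lines is not reported. For edge against core the same direction was required in every mouse instead, and this rule was applied literally to the interaction of position and line as well, which left 4 genes there. Lists (22 for mouse, 20 for rat and 24 for human) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 and again with an estimated correlation, Benjamini-Hochberg adjusted over the lists of an organism. Coordinates of mouse genes are from the GENCODE annotation of mm10. Near-identical copies share reads, so values for H2-K1, H2-D1 and the H2-Q genes, the haemoglobin, Gbp and Ifit families, and Reg3b and Reg3g are uncertain between members.

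Spot correlations were partial Spearman correlations of the UMIs per 10000 of 2 lists over spots with at least 500 UMIs, holding log10 total UMIs fixed, as 1 value per mouse, with an exact 2-sided sign-flip permutation test over 8 mice for 15 pairs. The same 15 pairs were compared between lines with an exact permutation of the line labels, a test outside the fixed design. Moran's I was computed over the 6 nearest lattice neighbours after each spot was thinned to 1000 UMIs. Library measures were compared with exact 2-sided permutation tests. Counting intervals are 95% and cover counting error only. A fold against a group with no counts used a floor of 3 counts over the group. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for loading, spots and plots.

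On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold in each design, edgeR recovered 35% and 82% for the comparison of lines, 33% and 79% for day, 0% and 16% for line by day, 87% and 94% for edge and core, 64% and 87% for position by line, 52% and 81% for FFPE, 92% and 96% for coverslip and 78% and 94% for the experiments, with 3 to 24 other genes called. Within each rat or mouse group no library was a copy of another (chi-square per degree of freedom from 3.24 to 494, where copies drawn from 1 library would give 1). Pairs across groups and the human libraries were not compared in this way. Alternatives were RLE size factors, no filter, DESeq2 1.42.0, no mitochondrial or ribosomal genes, other positions, samples, controls and spots, counts thinned to equal totals, leaving out each mouse or library, and, in the rat comparisons with shared letters, a block for the letter. Those with experiment 4 as the only control, or without the experiment 1 mouse libraries, were chosen after seeing the data.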

Results

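The series holds 29 Visium spatial transcriptomics libraries, in which RNA from a tissue section is captured on an array of barcoded spots and counted as unique molecular identifiers (UMIs), each spot covering several cells. The assay was run on 15 sections of rat colon, 11 sections of mouse tumours from 8 mice and 3 sections of human pancreatic ductal adenocarcinoma, 1 from each of 3 donors. The rat sections were fresh frozen in experiment 1 (4 libraries), experiment 2 (4 libraries) and experiment 4 (2 libraries titled with a coverslip during imaging and 2 without). Those of experiment 3 were formalin-fixed, paraffin-embedded (FFPE) with poly(A) capture (3 libraries). The mouse tumours were grown under the skin of the flank from B16F10 cells, a melanoma line, or MC38 cells, a colon carcinoma line. They were taken at day 10 (1 mouse of each line, each with 2 libraries) or day 16 (3 mice of each line, 1 B16F10 mouse with 2 libraries). Total UMIs under tissue ran from 6430508 to 28894530 in the rat libraries, from 13432576 to 86242199 in the mouse libraries, and were 72642473, 12286894 and 5332141 in donors A, B and C. The spots under tissue numbered 1124 to 1453 in rat, 1372 to 3600 in mouse and 2204 to 3232 in human sections.

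B16F10 and MC38 tumours at day 16 were compared to ask how far cell-type genes differed between the 2 lines in whole sections. B16F10 tumours carried the pigment programme of melanocytes, with Mlana, Tyrp1 and Dct, proteins of the melanosome and enzymes of melanin synthesis, raised by log2 differences of 11.26 to 12.14. MC38 tumours held far more transcript of the macrophage, T cell, fibroblast and interferon response lists and of both classes of antigen presentation genes. Which cells the transcripts came from was not tested. B16F10 tumours also had more haemoglobin transcript and more Car9, a carbonic anhydrase induced by low oxygen. In edgeR, 9013 of 15551 genes differed, 4513 higher in B16F10 and 4500 higher in MC38 (n = 3 mice per line). DESeq2 called 9506.

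All 12 melanocyte genes were higher in B16F10, and all 12 were also counted when adjusted over the list alone (list adjusted p = 3.09e-07 by camera, adjusted p = 0.471 with an estimated correlation). Mlana (ENSMUSG00000024806, chromosome 19, 29697824 to 29708634 in mm10) stood at 2737 ± 886 CPM (SD, n = 3) in B16F10 and 0.618 ± 0.793 (SD, n = 3) in MC38, a log2 difference of 12.14 (adjusted p = 8.11e-05). Tyrp1 stood at 4450 ± 274 against 1.61 ± 2.08 and Dct at 5008 ± 166 against 2.06 ± 2.65 CPM (SD, n = 3). Of genes outside the list, Gsta1, a glutathione transferase, rose by 11.50 ± 0.74 and Ptgds, which makes prostaglandin D2, by 11.32 ± 0.77 (log2, SE). Slc45a2, Trpm1, Tyr, Fkbp6, Syt4 and Gsdmc were also among the 12 genes with the largest increases, between 11.01 and 11.40. At the other end, Il1rl1, the receptor of interleukin-33, fell by 12.21 ± 0.51, and H19, an imprinted non-coding RNA (chromosome 7, 142575529 to 142578143), fell by 10.48 ± 0.59. Mmp9, a secreted gelatinase (chromosome 2, 164940780 to 164955850), fell by 9.34 ± 0.54 and Fosl1, a member of the AP-1 family, fell by 9.48 ± 0.32 in B16F10 relative to MC38. The remaining genes of this group were Shisal2b, Klra4, Osr1, Dcn, Sema3a, Sertad4, Medag and Arhgap22, with log2 differences from -11.73 to -8.54.

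Among myeloid and lymphoid lists, all 13 macrophage genes were lower in B16F10 over all genes and over the list alone (adjusted p = 3.09e-07, 0.471 with an estimated correlation). The complement gene C1qb stood at 15.4 ± 3.17 CPM in B16F10 against 620.5 ± 330 in MC38, and Arg1, arginase 1, had a log2 difference of -5.88. Of 13 T cell genes, 12 were lower and 1 was higher (adjusted p = 0.000418, 0.471 with an estimated correlation). Cd8a, the CD8 co-receptor, had a log2 difference of -4.70 and the T cell receptor constant region Trbc2 one of -3.80, whereas Lck, a kinase of the T cell receptor pathway, was higher by 1.08. Of 10 cytotoxic genes, 9 were lower (adjusted p = 0.000575, 0.471 with an estimated correlation), including the granule protease Gzmb at -6.43 and the chemokine Ccl5 at 11.9 ± 1.66 against 263 ± 126 CPM. The interferon gamma list had 19 of 20 members lower (adjusted p = 5.92e-07, 0.471 with an estimated correlation, with Psmb8, an immunoproteasome subunit, at -5.95). The type I interferon list had 13 of 13 lower (adjusted p = 4.28e-07, 0.471 with an estimated correlation, with Isg15 at 14.1 ± 1.66 against 334 ± 70.7 CPM). All 7 genes of MHC class I (adjusted p = 0.00077) and all 6 of MHC class II (adjusted p = 0.00222) were lower (0.471 for each with an estimated correlation), B2m by a log2 difference of -2.74 and Cd74, the invariant chain, by -5.10. Of the 8 neutrophil genes, 5 were lower (6 over the list alone, adjusted p = 0.0621). Of the 5 dendritic genes 4 were lower (adjusted p = 0.0635). Of the 4 B cell genes 2 were lower and 2 higher (adjusted p = 0.953), with Ighm at -4.17 and Cd79a at 2.99.

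In the stromal lists, 11 of 12 fibroblast genes were lower in B16F10 and 1 was higher (adjusted p = 0.00113, adjusted p = 0.471 with an estimated correlation). The proteoglycan Dcn had a log2 difference of -9.06 and the collagen Col3a1 one of -6.26. The endothelial list had 2 of 11 members higher (1 over the list alone) and none lower (adjusted p = 0.927), with Vwf, the von Willebrand factor, at 1.57. The mural list had 2 members higher and 1 lower of 7 (adjusted p = 0.548). The erythroid list had 5 of 5 higher (adjusted p = 0.00729, adjusted p = 0.471 with an estimated correlation), with Hbb-bs at 533 ± 243 against 31.2 ± 11.2 CPM. The hypoxia list was split, with 8 of 15 members higher and 4 lower (adjusted p = 0.359). Car9 stood at 249 ± 25.9 against 15.4 ± 2.17 CPM, and Egln3, an oxygen sensor, had a log2 difference of -3.52. In the proliferation list 5 of 15 members were higher, the replication licensing gene Mcm2 by 1.61 (adjusted p = 0.0502). Of 7 epithelial genes 6 were lower (adjusted p = 0.0248, adjusted p = 0.494 with an estimated correlation), with Krt19 at -4.61 and Krt8 at only 4.25 ± 3.88 CPM in MC38. The early response list had 1 member higher and 2 lower of 11 (adjusted p = 0.642). Among tissues around the tumour, 8 of 9 skeletal muscle genes (adjusted p = 0.128), 3 of 4 keratinocyte genes (adjusted p = 0.203) and 1 of 5 adipocyte genes (adjusted p = 0.359) were lower in B16F10, and the keratinocyte gene Sbsn was higher. All list calls rest on the preset correlation between genes, and none of the lists in any of the 8 comparisons passed with an estimated correlation.

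**Figure D1:**
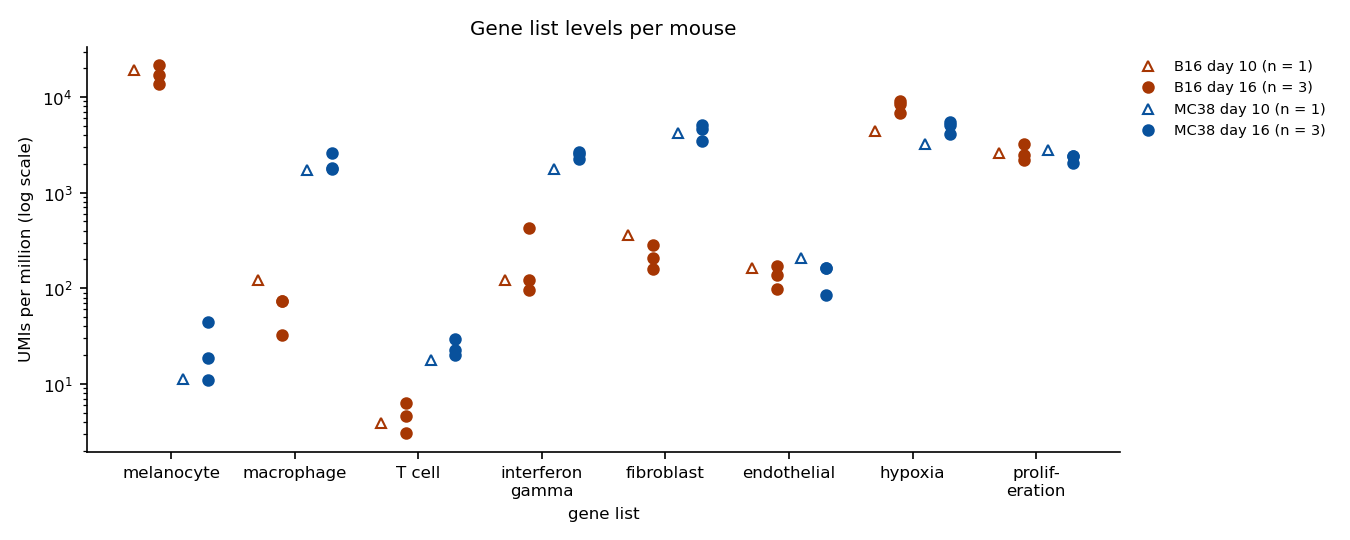
Summed CPM of 8 gene lists (log axis) in each of the 8 mice, with open triangles for day 10, filled circles for day 16, orange for B16F10 and blue for MC38. Macrophage genes sit between 32.8 and 121 CPM in the 4 B16F10 mice and between 1723 and 2610 in the 4 MC38 mice.

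Day 16 was compared with day 10 over both lines, with the line as a term, to follow the tumours as they grew. No single gene passed the threshold in edgeR, with 1569 of 16289 genes at an unadjusted p under 0.05. DESeq2 called 235 genes (159 higher and 76 lower at day 16) and limma over the 11 libraries, with experiment as a further term and the mouse as a random block, called 342 (252 higher and 90 lower). Only 1 mouse of each line was taken at day 10 (n = 2 against 6), and without mouse 2 edgeR called 1 gene. The hypoxia list moved as a group. All 15 hypoxia genes had positive estimates, 14 passed when adjusted over the list alone, and none passed over all genes (list adjusted p = 9.09e-23, adjusted p = 0.158 with an estimated correlation). Car9 had a log2 difference of 2.00 ± 0.22 (SE) with an adjusted p of 0.0621 over all genes, the lactate dehydrogenase gene Ldha one of 1.05 ± 0.28, and Pgk1, an enzyme of glycolysis, one of 0.93 ± 0.26. The 5 erythroid genes all passed over the list alone (list adjusted p = 2.81e-09, adjusted p = 0.340 with an estimated correlation), Hbb-bs with a difference of 3.53 ± 0.91.

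The type I interferon list was higher at day 16 as a set (adjusted p = 1.96e-07, adjusted p = 0.586 with an estimated correlation), with positive estimates for 13 of 13 genes of which 0 passed over the list alone. The interferon gamma list (adjusted p = 8.79e-05, 21 of 21 estimates positive, 1 gene over the list alone), the early response list (adjusted p = 1.94e-05, 2 genes, Hspa1b at 2.48 and Atf3 at 2.07) and MHC class I (adjusted p = 0.00176, 2 genes) were higher too, each at 0.586 with an estimated correlation. So were the T cell list (adjusted p = 0.0121, 4 genes, Cd3g at 2.00) and the cytotoxic list (adjusted p = 0.0111, 0 genes), again at 0.586 with an estimated correlation. The cytotoxic rise was seen in MC38, at 140 CPM at day 10 and 228 to 407 at day 16, and not in B16F10, at 16.3 and 8.87 to 15.7, with 1 mouse per line at day 10. Interferon gamma genes in B16F10 stood at 121 CPM at day 10 and at 96.3, 122 and 430 at day 16, clearly higher in mouse 4 only. In MC38 they stood at 1758 and 2228 to 2647. Early response genes in MC38 stood at 441 CPM at day 10 and at 282, 509 and 549 at day 16. In B16F10 they stood at 128 and 191 to 648. In B16F10 alone (1 mouse against 3) the cytotoxic list passed as lower (adjusted p = 0.00875 by camera), the type I interferon list pointed down (0.796) and the T cell list did not pass. Adipocyte genes were lower (adjusted p = 8.09e-05, 5 genes over the list alone), as were epithelial genes (adjusted p = 0.00646, 1 gene) and skeletal muscle genes (adjusted p = 0.0039, 0 genes), each at 0.586 with an estimated correlation. In MC38 alone (1 against 3) the epithelial list turned direction (adjusted p = 0.631 by camera) and the adipocyte and skeletal muscle lists did not pass. Without mouse 5, the MC38 mouse of day 10, the type I interferon list (adjusted p = 0.927) and the cytotoxic list (adjusted p = 0.0837) turned direction, and the T cell (0.158) and interferon gamma lists (0.0634) no longer passed. The cytotoxic list also missed the threshold without mouse 6 (adjusted p = 0.0596), and the T cell list without mouse 4 (0.0680) or mouse 7 (0.0548). Without mouse 1, the B16F10 mouse of day 10, the epithelial list turned direction (adjusted p = 0.720) and the skeletal muscle (0.585) and adipocyte lists (0.0562) no longer passed. The skeletal muscle list missed it without mouse 6 as well (adjusted p = 0.0549). The other lists did not pass, with adjusted p of 0.601 for melanocyte, 0.513 for B cell, 0.828 for macrophage, 0.311 for neutrophil, 0.289 for dendritic, 0.629 for MHC class II, 0.173 for fibroblast, 0.0501 for endothelial, 0.306 for mural, 0.0896 for proliferation and 0.341 for keratinocyte genes. The day 10 mice were in experiments 1 and 2 and the day 16 mice in experiments 2 and 3, so day and experiment overlapped only in experiment 2.

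Edge spots (1 or 2 lattice steps from the nearest position without tissue) were compared with core spots (6 or more steps) inside the same mice, to see how the tumour rim differed from its centre. The rim held more transcript of genes of the tissues around a flank tumour, with skeletal muscle myosins and the adipocyte genes Cfd and Car3 raised. It also held more of Col1a1 and Postn, matrix genes of fibroblasts, of the endothelial cadherin Cdh5 and of the inflammatory genes Il1b and Cxcl2. Transcripts encoded by the mitochondrial genome, such as mt-Co1, were higher at the rim in all 8 mice, and Nupr1, a stress-response gene, was lower in all 8. With edgeR and the mouse as a block, 611 of 13942 genes passed, 323 higher and 288 lower at the edge (n = 8 mice); DESeq2 called 808. The count was 62 in the 4 B16F10 mice alone (55 higher and 7 lower), 1189 in the 4 MC38 mice alone (746 and 443) and 48 in the 6 day 16 mice (41 and 7). With size factors by relative log expression the split was 301 higher and 137 lower, so the balance of directions moved with the scaling. The count also rested on single mice, since it fell to 174 without mouse 1, 236 without mouse 5, 181 without mouse 6, 132 without mouse 7 and 172 without mouse 8. Median UMIs per spot were lower at the edge than in the core in every mouse library. Of the 34 named genes past the threshold, 28 lost it when some single mouse was left out.

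Of the 9 skeletal muscle genes, 7 rose at the edge over all genes and 9 over the list alone (adjusted p = 1.65e-20, adjusted p = 0.0895 with an estimated correlation). The myosin heavy chain gene Myh1 (chromosome 11, 67200052 to 67224575) stood at 32.5 ± 36.0 CPM at the edge and 1.51 ± 1.70 in the core (SD, n = 8). The log2 difference was 4.32 ± 0.35 (SE), and the gene was higher at the edge in 7 of 8 mice. Of 4 adipocyte genes 3 rose, 4 over the list alone (adjusted p = 1.95e-07, adjusted p = 0.0895 with an estimated correlation), with Cfd at 3.27 and Car3 at 4.69. In the fibroblast list 3 of 12 rose, 4 over the list alone (adjusted p = 0.00289, adjusted p = 0.0895 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042) stood at 259 ± 255 against 57.3 ± 33.1 CPM, a difference of 1.65 ± 0.35, and Postn differed by 0.82 ± 0.17, each higher at the edge in 8 of 8 mice. The call for Col1a1 was lost when any of 7 single mice was left out, and that for Postn when any of the 8 was. In the neutrophil list 2 of 7 rose, 4 over the list alone (adjusted p = 1.25e-06, adjusted p = 0.0895 with an estimated correlation), Il1b by 0.81 and Cxcl2 by 1.70. In the endothelial list 3 of 11 rose, 8 over the list alone (adjusted p = 2.39e-06, adjusted p = 0.151 with an estimated correlation), with Cdh5 at 16.9 ± 6.50 against 11.7 ± 3.64 CPM.

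The epithelial list was higher at the edge (1 of 5 over all genes, 5 over the list alone, adjusted p = 1.41e-07, adjusted p = 0.0966 with an estimated correlation). So were MHC class II (0 of 6, 4 over the list alone, adjusted p = 1.57e-05 and 0.180 with an estimated correlation), the T cell list (0 of 9, 6 over the list alone, adjusted p = 5.83e-05 and 0.161), the mural list (0 of 7, 7 over the list alone, adjusted p = 8.24e-05 and 0.206) and the macrophage list (1 of 13, 3 over the list alone, adjusted p = 0.000293 and 0.274). The interferon gamma (adjusted p = 0.00289 and 0.414 with an estimated correlation), erythroid (adjusted p = 0.00796 and 0.337) and early response lists (adjusted p = 0.0401 and 0.438) were higher as sets with no single member past the threshold over all genes. The type I interferon list (adjusted p = 0.0013) and the proliferation list (adjusted p = 0.0241), both at 0.414 with an estimated correlation, were lower at the edge, again with no single member. In B16F10 mice alone the neutrophil, T cell and proliferation lists did not pass and the type I interferon list turned direction (adjusted p = 0.225 by camera), and in MC38 mice alone the fibroblast and macrophage lists did not pass. In day 16 mice alone the proliferation and early response lists did not pass. The early response list no longer passed without mouse 1 (adjusted p = 0.0943), mouse 3 (0.361) or mouse 6 (0.239). The interferon gamma list no longer passed without mouse 7 (adjusted p = 0.0805), nor the proliferation list without mouse 5 (0.0533) or mouse 7 (0.0805). The melanocyte (adjusted p = 0.936), cytotoxic (adjusted p = 0.155), B cell (adjusted p = 0.690), dendritic (adjusted p = 0.0853), MHC class I (adjusted p = 0.356), hypoxia (adjusted p = 0.690) and keratinocyte lists (adjusted p = 0.356) did not pass, although the basal keratin Krt14 rose by 1.40. Over all genes, 150 passed with at least a 2-fold rise at the edge. Outside the lists, genes were named only with a mean of at least 30 CPM and the same direction in all 8 mice. Under this rule 10 of the 12 largest increases were in mitochondrially encoded genes, from mt-Nd2 at 1.08 ± 0.22 to mt-Cytb at 0.67 ± 0.14. Of these mt-Co1, a subunit of cytochrome c oxidase, stood at 2856 ± 589 CPM at the edge and 1633 ± 442 in the core (SD, n = 8). Among genes lower at the edge, Nupr1 stood at 201 ± 118 against 296.5 ± 193 CPM, a difference of -0.49 ± 0.08. Fdps and Acly, enzymes of sterol and fatty acid synthesis, differed by -0.35 and -0.29. Arl6ip5, Coa3, Vegfb, Eef1akmt1, Ddt, Snrpd1, Cmc2, Rps4x and Zbtb8os completed the 12 largest decreases under the same rule, between -0.39 and -0.29.

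Whether the edge differed from the core in the same way in both lines was tested as the interaction of position and line. Tyrp1, a melanocyte gene, stood at 4445 ± 321 CPM at the edge and 4481 ± 313 in the core of B16F10 tumours, and at 4.92 ± 7.62 and 0.601 ± 0.926 in MC38 tumours (SD, n = 4 mice per line). Col3a1, a fibroblast collagen, stood at 55.0 ± 30.9 at the edge and 28.95 ± 11.1 in the core of B16F10 tumours but at 1937 ± 477 and 2512 ± 330 in MC38. The skeletal actin Acta1 stood at 39.1 ± 74.0 and 5.15 ± 7.03 in B16F10 and at 272 ± 219 and 8.00 ± 5.92 in MC38. In edgeR 324 of 13942 genes had a different edge effect (n = 4 mice per line), and DESeq2 called 416. The log2 difference of edge minus core was more positive in B16F10 for 74 of them and more positive in MC38 for 250, which does not say in which line it was larger in size. The count was 192 without mouse 3 and 205 without mouse 7. Of the 17 named genes past the threshold, 11 lost it when some single mouse was left out. Tyrp1 had an interaction of -3.02 ± 0.22, Dct of -2.99 ± 0.30, Ms4a7, a membrane protein of macrophages, of 1.40 ± 0.17 and Col3a1 of 1.24 ± 0.17 (log2, SE). Under the requirement of the same edge direction in every mouse, Tbx2 at 0.99 ± 0.20, Pmvk at 0.36 ± 0.09, Dstyk at 0.35 ± 0.08 and Mlph at -1.89 ± 0.36 were the genes outside the lists with the largest interactions. For Tbx2 the level was 91.0 at the edge and 96.5 in the core of B16F10 tumours and 4.14 and 8.50 CPM in MC38. Whether the change from day 10 to day 16 differed between the lines was tested in the same way. No gene passed in edgeR, with 732 of 16963 genes at an unadjusted p under 0.05, and DESeq2 called 48 (9 with a positive and 39 with a negative interaction, B16F10 minus MC38). Of the lists, 11 passed for the interaction of position and 14 for that of day with the preset correlation, and 0 with an estimated one.

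Correlations between gene lists over the spots of each tumour, with the total UMIs of the spot held fixed, were used to see which programmes shared places in the tissue. Hypoxia genes were low where proliferation genes were high, with a mean partial Spearman correlation of -0.331 over 8 mice (range -0.511 to -0.169, 0 of 8 mice positive, exact sign-flip permutation p = 0.00781, the smallest this test can give with 8 mice, and Benjamini-Hochberg adjusted p = 0.0117 over 15 pairs). The hypoxia list also ran against the endothelial list (-0.226), the macrophage list (-0.138) and the T cell list (-0.0896), each negative in 8 of 8 mice with the same exact p. Macrophage genes went with interferon gamma genes (0.235), T cell genes with MHC class II (0.164), interferon gamma (0.113) and macrophage genes (0.102). Fibroblast genes went with endothelial (0.201) and macrophage genes (0.145), and each of these 6 pairs was positive in 8 of 8 mice with an exact adjusted p of 0.0117. With spots thinned to 1000 UMIs the T cell pairs fell to 0.0207 for MHC class II, 0.0169 for interferon gamma, 0.0190 for macrophage, 0.00528 for cytotoxic and 0.00462 for proliferation genes, and hypoxia and T cell genes stood at -0.0144. None of these 6 pairs passed then. Weaker positive means were found for the T cell and cytotoxic lists (0.0823, 7 of 8 mice, exact adjusted p = 0.0195), the fibroblast and proliferation lists (0.0946, 7 of 8, exact adjusted p = 0.0195) and the T cell and proliferation lists (0.0275, 7 of 8, exact adjusted p = 0.0270). The hypoxia and neutrophil lists (-0.0214, exact adjusted p = 0.539) and the fibroblast and T cell lists (0.0256, exact adjusted p = 0.427) did not pass, although the latter passed without mouse 6 (0.0501). The T cell and proliferation pair no longer passed without any 1 of mice 1, 2, 3, 5, 7 and 8 (means from 0.0225 to 0.0284). T cell UMIs were scarcer in B16F10, which limits a correlation of the T cell list there. The mean correlation of T cell and MHC class II genes was 0.0437 in the 4 B16F10 mice and 0.284 in the 4 MC38 mice. That of macrophage and interferon gamma genes was 0.127 and 0.343 (exact permutation p = 0.0286, adjusted p = 0.0857 over 15 pairs for each of these and of 3 more pairs, so no difference passed).

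**Figure D2:**
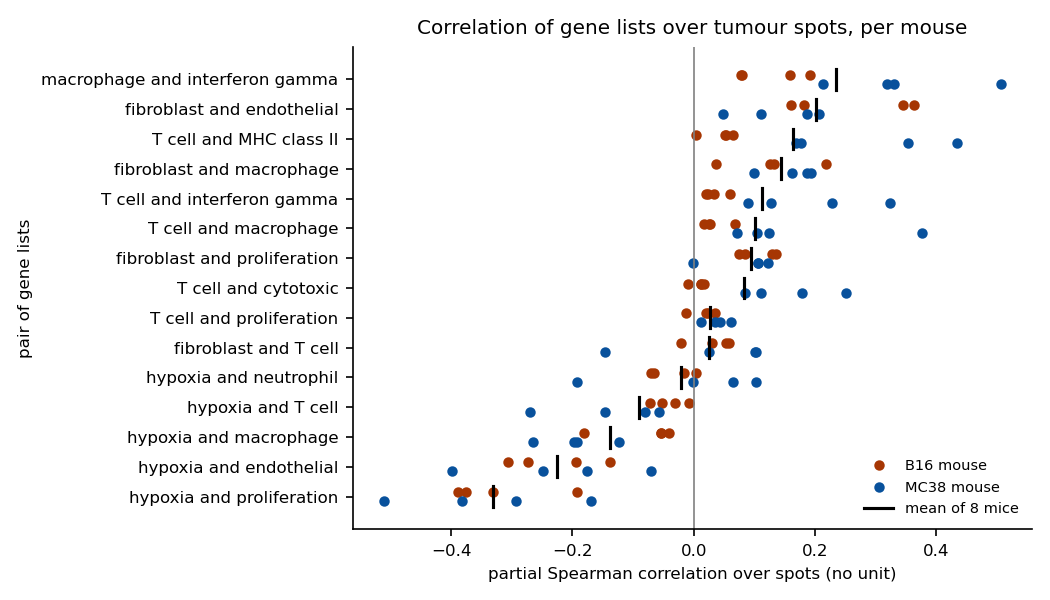
Partial Spearman correlation (x axis, no unit) between pairs of gene lists over the spots of each tumour, with 1 point per mouse in orange for B16F10 and blue for MC38 and a black bar for the mean of 8 mice. The mean runs from -0.331 for hypoxia and proliferation genes to 0.235 for macrophage and interferon gamma genes.

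FFPE rat colon with poly(A) capture was compared with the 8 fresh-frozen libraries of experiments 1 and 2, to see how libraries of the 2 preparations, made in separate experiments, differed. FFPE sections had less smooth-muscle transcript than these controls, with the gamma actin Actg2, the intermediate filament gene Des and the tropomyosin Tpm2 all lower, and more transcript of genes of cycling cells such as Top2a and Tyms. None of the 4 lists that passed here did so over all spots against experiment 4 alone, a control added after the data were seen. The antimicrobial lectins Reg3g and Reg3b were abundant in FFPE libraries and almost absent from fresh-frozen ones. Hoxb13, a homeobox gene of the distal gut, had no count in FFPE libraries, and it had none in the 4 fresh-frozen libraries of experiment 4 either. In edgeR 6753 of 12512 genes differed, 3332 higher and 3421 lower in FFPE (n = 3 and 8 libraries), and DESeq2 called 6915. Fixation was fully confounded with the experiment. Rat labels name no animals, so p-values for the rat data measure only the spread between libraries.

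Of 11 smooth-muscle genes, 10 were lower in FFPE (adjusted p = 6.02e-08, adjusted p = 0.351 with an estimated correlation), and the same number over the list alone. Actg2 (ENSRNOG00000029401) stood at 4386 ± 440 CPM (SD, n = 3) against 16830 ± 2474 (SD, n = 8), a log2 difference of -1.94 ± 0.16 (SE), and Des differed by -2.57 ± 0.16. The share of spots with more epithelium than smooth-muscle UMIs was 68.7% in FFPE and 31.8% in these controls (exact permutation p = 0.00606, 3 against 8 libraries), a measure added after the data were seen. Against the 4 libraries of experiment 4, where that share was 56.5% to 61.0%, differences over all spots were smaller, at -0.47 for Actg2, which missed the threshold, -1.01 for Des, -0.56 for Tpm2 and -0.51 for Tagln. In mucosal spots Actg2 (0.12), Tpm2 (0.27) and Tagln (0.33) turned to higher in FFPE against experiment 4, Tagln past the threshold, and Actg2 did in muscle spots (0.0482). Relative to all other genes, as camera tests it, the smooth-muscle list then pointed up and did not pass over all spots (adjusted p = 0.952) or in mucosal spots (0.111), and it passed as higher in muscle spots (0.0375). Mucosal and muscle spots were chosen by the UMIs of this same list, so its results within them are not independent of that choice. Of 14 proliferation genes 12 were higher (adjusted p = 8.49e-05, adjusted p = 0.351 with an estimated correlation), with Top2a, a topoisomerase of dividing cells, at 1.35 ± 0.09 and Tyms at 1.57 ± 0.27. Against experiment 4 the proliferation list did not pass (adjusted p = 0.0988 by camera), with Top2a at 0.88 and Tyms at 0.82 but Ube2c at -0.12 over all spots, -0.16 in mucosal and -0.35 in muscle spots. The adipocyte (0.154) and erythroid lists (0.319) did not pass against experiment 4 either. All 5 adipocyte genes were higher (adjusted p = 0.00732, adjusted p = 0.390 with an estimated correlation), Plin1, a lipid droplet protein, by 6.37 and Adipoq by 3.69. Of 5 erythroid genes 4 were lower (adjusted p = 0.0207, adjusted p = 0.351 with an estimated correlation), with Hba-a3 at -4.11.

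The other 16 rat lists did not pass in this comparison, with adjusted p of 0.0635 for macrophage (7 higher and 1 lower of 12), 0.0695 for early response (0 and 6 of 9), 0.0903 for enteric nervous (1 and 6 of 10), and 0.173 for epithelium (4 and 1 of 11). It was 0.173 for mast cell, 0.202 for endothelial, 0.280 for fibroblast, 0.491 for histone and 0.839 for goblet genes, and 0.991 for the colonocyte, stem, enteroendocrine, B cell, plasma, T cell and nuclear oxidative phosphorylation lists. Within them Epcam, an adhesion molecule of epithelia, rose from 1843 ± 295 to 4221 ± 182 CPM. The goblet genes Agr2 and Tff3 differed by 1.19 and -1.12 (1.64 and -1.59 against experiment 1 alone, 0.83 and -0.44 against experiment 2 alone). The colonocyte genes Car1 and Aqp8, a carbonic anhydrase and a water channel, differed by 3.61 ± 1.05 and -6.50 ± 0.24. Reg3g stood at 321.5 ± 173 CPM in FFPE, with 7274 counts against 1, a ratio of 40850 (95% counting interval 7331 to 1613000), and Reg3b had 4222 counts against 1, a ratio of 23710 (4255 to 936400). Osr2, a transcription factor, stood at 195 ± 5.93 against 0.801 ± 0.358 CPM, and Fabp1, a fatty acid carrier, rose by 6.63 ± 1.25. Napsa, Cxcl11, Cyp2c24, Tex49, Hoxb7, Gcnt3 and Mcpt2 rose by 2.84 to 5.30. Against experiment 1 alone and experiment 2 alone the rises were 11.07 and 5.65 for Fabp1, 5.82 and 4.89 for Napsa, 5.815 and 2.62 for Cxcl11, 7.88 and 2.40 for Cyp2c24, 4.33 and 2.62 for Tex49, 2.11 and 5.83 for Hoxb7, 4.14 and 2.24 for Gcnt3, 3.68 and 2.30 for Mcpt2 and 7.19 and 2.66 for Car1. The gap was smaller against experiment 4, where Car1 stood at 4932 to 5588 CPM, against 11080 to 12140 in FFPE (without TMM factors). Hoxb13 was at least 2932-fold lower in FFPE against a floor of 3 counts over the group, with 3.207 to 633.2 CPM in the 8 controls. Sval1 (1 count in FFPE, ratio 12410, 2228 to 490200), Fxyd4 (2 counts, ratio 10180, 2819 to 84100), Tgm3 (2 counts, ratio 6268, 1735 to 51760) and Sftpd (3 counts, ratio 2070, 708 to 10040) were lower as well. These ratios pool controls that differ widely, as Fxyd4 stood at 1466 CPM in experiment 1 and 0.823 in experiment 2. With experiment 2 alone as control the log2 differences were -7.72 for Tgm3 and -3.175 for Sftpd. Of the 74 named genes past the threshold 18 lost it when some single library was left out, among them Hoxb13, Hoxd13, Sval1, Fxyd4 and Sftpd. Hoxd13, B3gnt7, Slc37a2, Tnnc2, Apoa1 and Txn1 had differences from -6.70 to -4.90. Sizes depended on the control here too, with -7.64 against experiment 1 alone and -2.51 against experiment 2 alone for Hoxd13, -7.60 and -3.26 for B3gnt7, -6.64 and -0.739 for Slc37a2, -6.28 and -3.47 for Tnnc2, -5.51 and -4.52 for Apoa1, and -3.89 and -5.515 for Txn1. In the fresh-frozen libraries of experiment 4, Hoxd13 stood at 0.771 to 1.25 CPM without TMM factors. That range overlapped the 0.311 to 1.27 of the FFPE libraries.

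Median UMIs per spot averaged 6283 in FFPE and 11769 in fresh-frozen libraries (exact permutation p = 0.0182, adjusted p = 0.0273) and median genes per spot 2319 and 3353 (exact p = 0.00606). After each spot was thinned to 1000 UMIs the means were 628 and 629 genes, and no difference was found (exact p = 0.897). Mitochondrially encoded genes took 14.8% of UMIs in FFPE and 8.88% in fresh-frozen libraries (exact p = 0.00606). Spatial autocorrelation (Moran's I, thinned spots) was 0.656 in FFPE and 0.842 in fresh-frozen sections for smooth-muscle genes, 0.437 and 0.587 for goblet genes, 0.640 and 0.430 for colonocyte genes and 0.296 and 0.195 for enteric nervous genes. None of the 9 lists passed (lowest adjusted p = 0.0545, exact permutation). Smooth-muscle genes reached the smallest p this test can give for 3 against 8 libraries (0.00606). A list alone at that p cannot pass when adjusted over 9 lists. In experiment 4, a control added after the data were seen, Moran's I was 0.688 for smooth-muscle, 0.487 for goblet, 0.602 for colonocyte and 0.165 for enteric nervous genes, so the first 3 differences from FFPE shrank. The smooth-muscle difference passed without library B or C of experiment 1 (-0.185 and -0.188), that of goblet genes without library C of experiment 1 (-0.181) and that of enteric nervous genes without library B of experiment 1 (0.110). Without FFPE library C the difference in UMIs per spot was -4428 and no longer passed.

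The coverslip comparison set 2 libraries of experiment 4 titled with a coverslip against 2 titled without, to see what covering the section during imaging changes. File names give the opposite assignment, so every direction here follows the titles. Smooth-muscle genes, among them Des and Cnn1, and genes of enteric nerves and glia, such as Uchl1 and Gfap, were higher with the coverslip. Spink4, a goblet cell inhibitor of proteases, and Chgb and Tph1, genes of hormone-secreting cells, were lower. The share of spots with more epithelium than smooth-muscle UMIs was 56.5% and 58.1% with the coverslip and 61.0% and 59.7% without. This share is counted from the UMIs of the smooth-muscle list itself, so it is not independent of the rise of that list. It cannot show whether the content of the sections differed. In edgeR 328 of 12198 genes passed, 251 higher and 77 lower with the coverslip (n = 2 and 2), and DESeq2 called 211. The count was 2 without library A, 41 without library B, 1002 without library C and 925 without library D, the lone library of a group being assumed to vary like the pair. It was 15 with all 10 uncovered fresh-frozen libraries in the fit and experiment as a term, where the coverslip effect still came from experiment 4 alone. All 33 named genes past the threshold lost it when some single library was left out.

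Of 11 smooth-muscle genes 6 rose, 9 over the list alone (adjusted p = 1.61e-09, adjusted p = 0.479 with an estimated correlation), with Des at 0.71 ± 0.11 and Cnn1 at 0.69 ± 0.12 (log2, SE). Of 10 enteric nervous genes 5 rose, 7 over the list alone (adjusted p = 1.91e-08, adjusted p = 0.479 with an estimated correlation), with Uchl1 at 0.60 and Gfap at 1.04. Of 7 enteroendocrine genes 3 fell, 4 over the list alone (adjusted p = 0.000329, adjusted p = 0.479 with an estimated correlation), Chgb by a difference of -0.46 and Tph1 of -0.45. Of 8 goblet genes 1 fell, 2 over the list alone (adjusted p = 0.0057, adjusted p = 0.5775 with an estimated correlation), which was Spink4 at -0.64 ± 0.10. The endothelial list (adjusted p = 0.00711 and 0.479 with an estimated correlation) had 2 genes higher, Cldn5 by 0.50 and Egfl7 by 0.48, and the adipocyte list (adjusted p = 0.00711 and 0.5775) had none. The proliferation (adjusted p = 0.0057) and B cell lists (adjusted p = 0.0320) were lower with no member past the threshold over all genes, both at 0.479 with an estimated correlation. Without library A the goblet (adjusted p = 0.0619), endothelial (0.0619) and adipocyte lists (0.276) no longer passed. The adipocyte list missed it without library C as well (adjusted p = 0.0907), and the B cell list without library B (0.2685). The remaining 12 lists did not pass, at adjusted p of 0.0556 for epithelium and plasma, 0.0651 for mast, 0.0787 for macrophage, 0.0794 for erythroid, 0.104 for colonocyte and early response, 0.266 for nuclear oxidative phosphorylation, 0.328 for histone, 0.369 for T cell and 0.999 for stem and fibroblast genes. Outside the lists Slc2a4, an insulin-responsive glucose transporter, rose by 0.95 ± 0.09, and Itga7, Igfbp2, Speg, Ckm, Myl9, Prph, Itga5, Fbxl22 and Il11ra1 by 0.70 to 0.83. The genes Atp5me, Tmem258b, Ndufb4, Rps21, Mt2A, Atp5md, Lyz2, Rpl36, Rpl36al and Igfbp3 fell, with differences from -0.54 to -0.43. Median UMIs per spot were 11104 and 14269 (exact permutation p = 0.667, and 0.333 is the smallest p for 2 against 2).

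Experiments 1 and 2 are both labelled fresh frozen, and they were compared to see how far libraries of separate experiments differ. Sections of experiment 2 had more transcript of genes of absorptive cells, with the carbonic anhydrases Car1 and Car2 and the sodium exchanger Slc9a3 raised, and more of hormone-secreting cells. Sections of experiment 1 had the proton pump gene Atp12a, the ion transport regulator Fxyd4, the calcium-binding S100g and Hoxb13 at 629 to 6061 CPM, all much lower in experiment 2. In edgeR 5928 of 12240 genes differed, 3010 higher and 2918 lower in experiment 2 (n = 4 and 4), and DESeq2 called 5665.

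All 7 enteroendocrine genes were higher in experiment 2 (adjusted p = 1.08e-05, adjusted p = 0.163 with an estimated correlation), among them the granin Chga at 2.91 ± 0.16 and Gcg, which encodes glucagon-like peptides, at 2.63 ± 0.08. All 9 early response genes were lower (adjusted p = 1.08e-05, adjusted p = 0.163 with an estimated correlation), with Fos at -2.12 and Junb at -1.43. Of 12 colonocyte genes 8 were higher and 1 lower (adjusted p = 9.94e-05, adjusted p = 0.223 with an estimated correlation). Car1 stood at 1879 ± 190 CPM in experiment 2 and 82.5 ± 9.75 in experiment 1 (SD, n = 4). Of 8 goblet genes 6 were higher and 2 lower (adjusted p = 0.0202, adjusted p = 0.163 with an estimated correlation), Spink4 by 10.26 ± 0.49 and Zg16 by 3.42, while Tff3 differed by -1.17. The enteric nervous (8 of 10 higher, adjusted p = 0.00482), B cell (3 of 3 higher, adjusted p = 0.0205, Ighm at 2.16) and mast cell lists (4 of 5 higher, adjusted p = 0.0361, Cpa3 at 1.41) passed too, at adjusted p of 0.163 to 0.432 with an estimated correlation. The mast cell list no longer passed without library D of experiment 1 (adjusted p = 0.0571). The other 13 did not, at adjusted p of 0.0571 for adipocyte, 0.122 for T cell, 0.182 for macrophage and histone, 0.329 for fibroblast, endothelial and plasma, 0.378 for proliferation, 0.671 for epithelium, 0.813 for stem, 0.815 for smooth-muscle and erythroid, and 0.872 for nuclear oxidative phosphorylation genes.

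Atp12a stood at 0.176 ± 0.147 CPM in experiment 2 and 823 ± 35.0 in experiment 1 (SD, n = 4), a difference of -11.99 ± 0.21, and Fxyd4 at 0.823 ± 0.0668 against 1466 ± 85.5. S100g stood at 60.1 ± 5.40 against 6061 ± 287 and Hoxb13 at 3.93 ± 0.950 against 629 ± 8.71 CPM. Scgb1a1, Mptx1, Sval1, Sftpd, Chst5, Slc37a2, Tgm3 and Spink1 fell too, with differences from -10.84 to -5.50. Ghrl, which encodes the hormone ghrelin, had 1 count in experiment 1, a ratio of 5544 (95% counting interval 995 to 219000), and Cyp4f1, Sptssb, Cyp2c24, Dpep1, RT1-Bb and Cldn15 rose by 3.94 to 8.92. Median UMIs per spot averaged 9261 in experiment 2 and 14276 in experiment 1, and median genes per spot 3039 and 3668 (exact permutation p = 0.0286, adjusted p = 0.0857 for each). Genes per spot after thinning averaged 643.5 and 615 (exact p = 0.0857), and the difference passed without library C of experiment 1 (36.5).

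**Figure D3:**
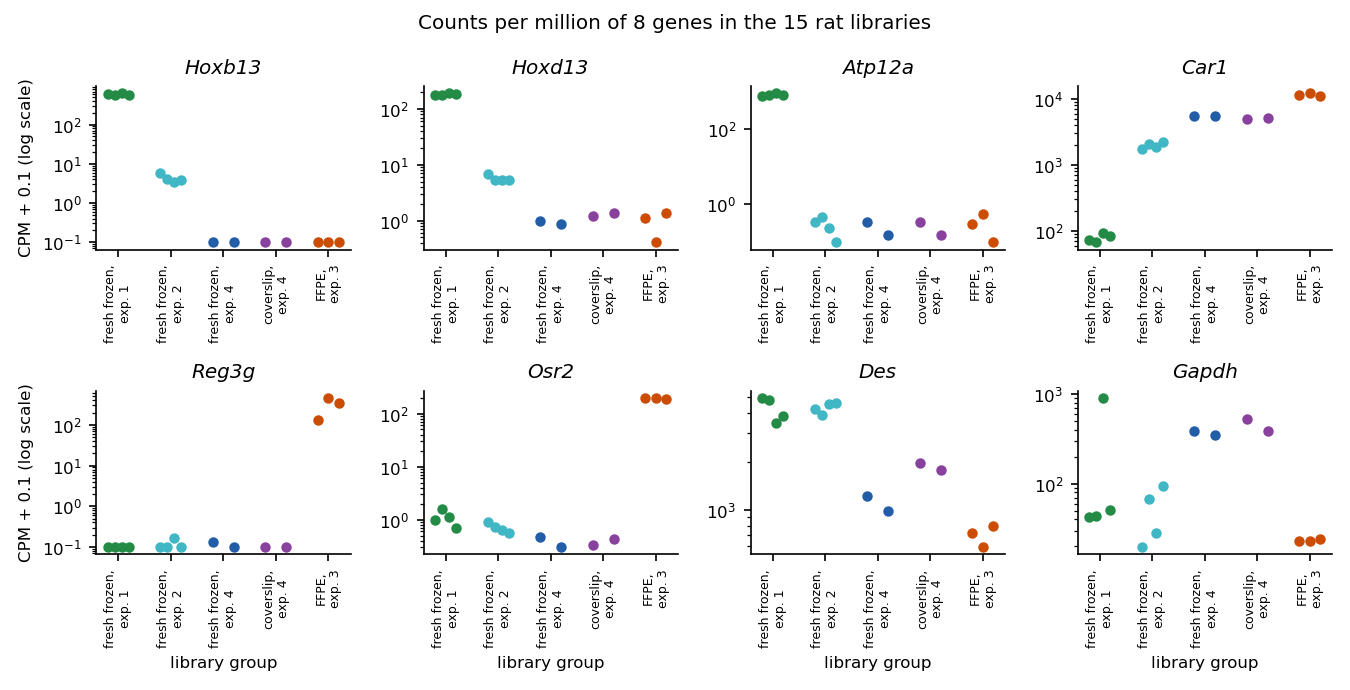
Levels in CPM (not TMM-scaled, plus 0.1, log axis) of 8 genes in the 15 rat libraries, 1 point per library, grouped by experiment and preparation; the 8 genes were chosen after their values were seen. Hoxb13 sits between 583 and 628.5 in experiment 1, between 3.31 and 5.61 in experiment 2 and at 0 in experiments 3 and 4. Gapdh sits at 897 in library C of experiment 1 and between 42.5 and 51.0 in its other libraries.

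The human sections were profiled with a probe panel on FFPE tissue, and the 3 donors were described without a test because there were no groups among them. Acinar genes of the exocrine pancreas differed most, at 124000 CPM in donor A, 1122 in donor B and 43.5 in donor C. In donor A the pancreatic lipase PNLIP and the carboxypeptidase CPB1 alone gave 17180 and 14230, and in donor B REG1A alone gave 874 of the 1122. Fibroblast genes stood at 14490, 9917 and 52015 CPM and myofibroblast genes at 2214, 9387 and 11220. Genes of the classical tumour programme stood at 6263, 7111 and 1711 CPM and those of the basal-like programme at 213, 1250 and 323, with S100A2, a calcium-binding protein, giving 788 of the 1250 in donor B. The human counts held 16 of the 20 basal-like genes, without KRT6A, KRT6C, KRT17 and SERPINB4. They held 21 of the 22 classical genes, without CEACAM6. KRT19 was missing from the epithelial list and LDHA from the hypoxia list. Epithelial genes stood at 2708, 4272 and 2764 in donors A, B and C, islet genes at 701, 367.5 and 34.0, inflammatory fibroblast genes at 1952, 898 and 1272, endothelial genes at 577, 350.5 and 368 and nerve genes at 141, 155 and 139. Immune lists in the same order stood at 162, 107 and 190 for T cell, 67.1, 88.6 and 204 for cytotoxic, 34.9, 32.5 and 17.6 for B cell and 187, 173 and 116 for lymphoid chemokine genes. They stood at 1346, 1076 and 110 for plasma, 3848, 1346 and 1782 for macrophage, 385, 824 and 1179 for neutrophil, 107, 37.6 and 26.3 for mast cell, 3764, 2182 and 2710 for MHC class II and 935, 957 and 1003 for interferon gamma genes. In donor A the single gene SPP1 gave 2291 of the 3848 of the macrophage list. Hypoxia genes stood at 863, 1143 and 1176, proliferation genes at 260.5, 875 and 570, adipocyte genes at 12.7, 7.73 and 8.82 and hepatocyte genes at 732, 512 and 127.5 CPM. SERPINA1 alone gave 670, 504 and 126 of the hepatocyte levels in donors A, B and C, so list levels do not measure cell content. Moran's I was 0.896, 0.486 and 0.0603 for acinar genes and 0.689, 0.582 and 0.824 for fibroblast genes. Acinar genes were scarce in donor C, which limits their Moran's I there. Donor A had a median of 30740 UMIs per spot, donors B and C 2281.5 and 2239, so scarce lists such as the B cell list rest on fewer counts in donors B and C.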

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

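Of the tests in this part, those of mouse RNA in library C of experiment 1 and of experiment or block in the FFPE comparison were chosen after the result was seen, and Hoxb13 and Hoxd13 were picked after their levels in whole libraries had been seen.

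Rat fresh-frozen experiments 1 and 2 differed in 5928 genes. Animals and blocks are not labelled, so splits of the libraries cannot exclude chance differences between animals. An arbitrary grouping of libraries is argued against, since 1 of the 35 splits of the 8 libraries gave as many genes and the highest other split gave 0. Sequencing depth does not account for the difference, as 5235 genes passed after all libraries were thinned to equal totals. Nor does the share of mucosal and muscle spots, as 5171 genes passed in spots with more epithelium than smooth-muscle UMIs and 4250 in the others. A difference in position along the colon is a candidate explanation, because the posterior homeobox genes Hoxb13 and Hoxd13 fell in both kinds of spots, Hoxb13 by -7.40 and -7.06 and Hoxd13 by -8.27 and -3.74 (log2). This may be biological, but it remains a hypothesis since the animal and the colon segment are not labelled and other differences between the experiments stay open.

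Library C of experiment 1 stood apart from libraries A, B and D, with 144 genes at least 3-fold above every other library of the experiment (0 such genes for A, B or D) and 18 below (0 for the others). Rpl37 stood at 1353 CPM against at most 69.5, Eef1a1 at 1050 against at most 110 and Gapdh at 897 against at most 51.0, although Gapdh stood at 346 to 530 in experiment 4 too. A different share of mucosal and muscle spots is argued against, since the median log2 ratio was 2.29 in mucosal and 2.375 in muscle spots. RNA from the mouse tumours is argued against too, since it would have to make up 40.5% of the library, and the 94 abundant mouse genes which that would at least double rose by a median of 0.00171 of the needed rise (upper quartile 0.0763). Reads shared with near-identical copies stay open, as 27 raised genes had a named pseudogene copy against 19 of equally many genes of like expression (Fisher's exact p = 0.260), and neither a different annotation nor a biological explanation was tested.

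FFPE and fresh-frozen rat libraries differed in 6753 genes. Splits of libraries cannot exclude chance differences between animals or blocks, which are not labelled. An arbitrary grouping of libraries is argued against, since 1 of the 100 splits tried gave as many genes and the highest other split gave 654. That split set libraries A, B and D of experiment 1 apart, and the next set libraries A, C and D of experiment 1 apart with 559, which points to a structure by experiment. More mucosal spots in the FFPE sections do not account for all of it, as 4763 genes passed in mucosal spots and 3864 in muscle spots. Fixation and the experiment or block of tissue cannot be told apart, since all FFPE libraries are from 1 experiment. Of the 6753 genes, 4197 had all FFPE libraries outside the range of all 12 fresh-frozen libraries (2061 above and 2136 below), but genes already called as different favour such a count, and any difference between blocks could give it as well.

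Other values stood out without being explained here. Dixon's test was applied to 100 groups of 4 or more samples and marked 6 values, where chance marks about 5. Library C of experiment 1 had a median of 639 genes per spot after thinning, against 605 to 609 in the others of its group. The histone list stood at 88.4 CPM in library C of experiment 1 and at 14.3 to 17.5 in the others. The plasma cell list stood at 44.8 CPM in library B of experiment 2 and at 29.3 to 31.3 in the others. The nuclear oxidative phosphorylation list stood at 1.29e+04 CPM in library B of experiment 2 and at 1.249e+04 to 1.255e+04 in the others. The correlation of fibroblast and proliferation genes was -0.00112 in mouse 5 and 0.106 to 0.122 in the other MC38 mice. The correlation of hypoxia and macrophage genes was -0.181 in mouse 2 and -0.0540 to -0.0403 in the other B16F10 mice.

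The edge effect differed between the lines in 324 genes, by the test of the interaction itself. An arbitrary grouping of the mice is argued against, since 1 of the 35 splits of the 8 mice gave as many genes and the highest other split gave 5. So few splits cannot exclude chance. Lists whose edge minus core difference was more positive in MC38 were melanocyte (adjusted p = 4.27e-13, 9 of 12 genes), skeletal muscle (4.87e-13, 2 of 9), mural (6.61e-07, 1 gene, Myh11 at -3.08), neutrophil (0.00761, 1 gene, G0s2 at -3.06), adipocyte (0.00761, 1 gene, Car3 at -2.78), endothelial (0.0198, 1 gene, Plvap at -0.71) and erythroid (0.0294, 0 genes). Those more positive in B16F10 were macrophage (adjusted p = 9.23e-09, 2 of 13 genes), type I interferon (0.00435, 1 gene, Oasl2 at 1.03), fibroblast (0.00444, 3 of 12) and keratinocyte (0.0356, 1 gene, Krt10 at 2.30). With an estimated correlation these 11 lists had adjusted p from 0.130 to 0.561. Single mice decided some of these calls. Without mouse 1 the fibroblast list had an adjusted p of 0.143, without mouse 3 the type I interferon list 0.0625 and without mouse 6 the erythroid list 0.307. Without mouse 7 the endothelial list had 0.101 and without mouse 8 the neutrophil list 0.05225. The keratinocyte list no longer passed without mouse 1, 4, 5, 7 or 8 (adjusted p from 0.05225 to 0.496), nor the type I interferon list without mouse 1 (0.0614) or mouse 8 (0.05225), nor the endothelial list without mouse 3 (0.0633). The lists that did not pass were epithelial (0.611), T cell (0.481), cytotoxic (0.556), B cell (0.295), dendritic (0.611), interferon gamma (0.340), MHC class I (0.277), MHC class II (0.611), hypoxia (0.0841), proliferation (0.122) and early response (0.676).

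In the test of the interaction of line and day, 14 lists passed with the preset correlation and 0 with an estimated one. Each line had 1 mouse at day 10, so a difference in day effect cannot be told apart from that mouse. The log2 change from day 10 to day 16 was more positive in B16F10 for hypoxia (adjusted p = 2.96e-08), erythroid (2.26e-06), proliferation (0.00129) and early response genes (0.00707). It was more positive in MC38 for epithelial (adjusted p = 6.85e-10), type I interferon (1.90e-09), macrophage (2.96e-08), keratinocyte (3.52e-07), cytotoxic (6.82e-07), adipocyte (2.28e-06), skeletal muscle (4.61e-06), fibroblast (0.000513), melanocyte (0.00707) and MHC class II genes (0.00707). Such a difference can be a fall in B16F10, as for epithelial genes at 21.8 CPM at day 10 and 0.669 to 2.32 at day 16, against 18.8 and 7.015 to 24.2 in MC38. It can also be a rise in MC38, as for type I interferon genes at 1054 and 1909 to 2270, against 210.2 and 145 to 271.5 in B16F10. With an estimated correlation these lists had adjusted p from 0.2725 to 0.529. The early response list no longer passed without mouse 6 (adjusted p = 0.0511), the melanocyte list without mouse 8 (0.0764) and MHC class II without mouse 2 (0.0778) or mouse 3 (0.0672). The lists that did not pass were T cell (0.571), B cell (0.905), neutrophil (0.292), dendritic (0.0884), interferon gamma (0.411), MHC class I (0.873), endothelial (0.100) and mural (0.736).

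For B16F10 against MC38 at day 16 the 6 mice allow 10 splits, too few for a share under 0.05, with 9013 genes for the real split and 0 for the highest other. For edge against core, arbitrary labels of edge and core are argued against, since 1 of the 100 splits tried gave as many as 611 genes. The highest other split, with edge and core exchanged in mouse 4, gave 219. Chance is not excluded by this, and leaving out 1 mouse at a time gave 132 to 821 genes.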

How the results depend on the processing

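Among the settings here, those with experiment 4 libraries as the only control of the FFPE comparison and those without the experiment 1 mouse libraries were chosen after the data were seen. So were the percentage of mucosal spots and the number of tissue spots, which entered the adjustment of p over the measures of depth in the rat comparisons. Simulated 2-fold changes were recovered by edgeR for 33% of genes in the day comparison and for 0% in the interaction of line and day, where 1 mouse per line was taken at day 10. Where a value changed, the cause was not tested. Whether the letters of the rat libraries pair them is not settled. Same-letter correlations between experiments 1 and 2 ran from -0.341 to 0.433 (1 of 4 libraries correlated best with its own letter). Between experiment 1 and FFPE they ran from -0.0495 to 0.0225 (1 of 3). Between experiment 2 and FFPE they were low, from 0.0618 to 0.0823, but 3 of 3 libraries correlated best with their own letter. With the letter as a replicate block the FFPE comparison gave 5538 genes and the comparison of experiments 5112. No paired fit was possible for the coverslip, where the letters differ between groups.

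The comparison of lines at day 16 kept its count within 1.5 times in every setting, and under the planned settings 8 of its 84 named genes past the threshold lost the call. At least 1 setting changed the call of 46 of 74 named genes for FFPE, 33 of 33 for the coverslip, 15 of 73 for the experiments, 32 of 34 for edge and core and 13 of 17 for position by line. Apart from the estimated correlation, which left 0 lists past the threshold in all 8 comparisons, at least 1 setting changed 2 of 11 lists for the lines, 9 of 11 for day, 3 of 14 for line by day, 12 of 15 for edge and core, 6 of 11 for position by line, 4 of 4 for FFPE, 4 of 8 for the coverslip and 1 of 7 for the experiments.

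Counts of genes moved by more than 1.5 times as follows. With no filter on low counts, day gave 2 genes, edge and core 2147 (579 higher and 1568 lower), position by line 651 and the coverslip 823. DESeq2 gave 235 for day, 48 for line by day and 211 for the coverslip. For day, B16F10 mice alone gave 2 and libraries with an experiment term and the mouse as a random block, fitted by limma, 342. For edge and core, B16F10 mice gave 62, MC38 mice 1189, day 16 mice 48 and the set without the experiment 1 libraries 404. Muscle spots gave 3864 for FFPE, and all 10 uncovered libraries with experiment as a term gave 15 for the coverslip. Leaving out 1 mouse or library at a time gave 0 to 1 for day, 132 to 821 for edge and core, 192 to 370 for position by line and 2 to 1002 for the coverslip. Lists past the threshold numbered 6 for day with the experiment term and random block, 6 for edge and core with no filter, and 13 for the coverslip with no filter and 5 to 12 without 1 library. For FFPE they numbered 7 with no filter, 7 with experiment 1 as control, 7 with experiment 2, 2 with experiment 4 and 2 with its mucosal spots. For FFPE, dropping the filter moved the median log2 difference of all genes from -0.045 to -0.218.

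Lists turned direction in these settings, with adjusted p after the turn. For day these were the epithelial list in MC38 mice alone (0.631), the cytotoxic (0.00875) and type I interferon lists (0.796) in B16F10 mice alone, and the skeletal muscle list without the experiment 1 libraries (0.5485). Each line had 1 mouse at day 10, so a turn within a line cannot be read as an effect of day. Leaving out 1 mouse turned 3 lists, with values over all 8 mice left out from 1.86e-10 to 0.720 for epithelial, 3.91e-06 to 0.0837 for cytotoxic and 2.28e-14 to 0.927 for type I interferon genes. For edge and core they were interferon gamma with no filter (0.978) and type I interferon in B16F10 mice (0.225). For FFPE they were smooth muscle against experiment 4 in all (0.9515), mucosal (0.111) and muscle spots (0.0375), and erythroid in mucosal spots (0.693). The smooth-muscle list helps to define mucosal and muscle spots, so its turns within them are not independent of that choice.

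Named rat genes past the threshold that turned are given with the log2 difference after the turn. Actg2, Tagln, Tpm2, Krt8 and Vil1 belong to the lists that define mucosal and muscle spots, so their values there are not independent of that choice. For FFPE, Plvap stood at -0.0344 with all 12 fresh-frozen controls and -0.0592 in mucosal spots, and in muscle spots Lck stood at -0.16 and Atp5f1b at -0.00557. Against experiment 4, Ube2c stood at -0.12, Lum at 0.47, Plvap at -0.36 and Lck at -0.42. In mucosal spots against experiment 4, Agr2 stood at -0.0216, Ube2c at -0.16, Actg2 at 0.12, Tagln at 0.33, Tpm2 at 0.27, Uchl1 at 0.14, Lum at 0.70, Plvap at -0.38, Lck at -0.40, both Hba-a2 genes at 0.57 and 0.29, and Jun at 0.32. In muscle spots against experiment 4, Hoxd13 stood at 0.48, Ube2c at -0.35, Actg2 at 0.0482, Uchl1 at 0.47, Lum at 0.78, Plvap at -0.54, Lck at -1.04, RT1-Da at -0.11, Cpa3 at -0.49, Hspa1b at 0.0858, Atp5f1b at -0.25 and Sdhb at -0.19. For the experiments, Krt8 stood at 0.02996, Smoc2 at 0.0690, Cldn5 at 0.0744 and Hba-a3 at -0.42 in mucosal spots, and Vil1 at -0.12 in muscle spots.

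Thinned spots held few T cell UMIs, so the T cell pairs there cannot separate depth from scarcity. Spot correlations in the mouse tumours changed as follows. With thinned spots the means no longer passed for hypoxia and T cell (-0.0144), T cell and interferon gamma (0.0169), T cell and macrophage (0.0190), T cell and MHC class II (0.0207), T cell and cytotoxic (0.00528) and T cell and proliferation genes (0.00462), and that of hypoxia and neutrophil genes turned (0.00405). With no depth control that of T cell and proliferation genes was 0.0127. Leaving out 1 mouse at a time gave means of 0.0225 to 0.0333 for T cell and proliferation, 0.0145 to 0.0501 for fibroblast and T cell and -0.0392 to 0.003005 for hypoxia and neutrophil genes.

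Differences in Moran's I between FFPE and fresh-frozen sections passed with no thinning for epithelium (-0.175), goblet (-0.274), smooth muscle (-0.0998) and endothelial genes (-0.103), and that of fibroblast genes turned (-0.00780). With no thinning the differences shrank from 0.209 to 0.0168 for colonocyte genes and from 0.100 to 0.0475 for enteric nervous genes. Against experiment 4 those of epithelium (0.182), proliferation (0.0225) and endothelial genes (0.0195) turned, and against experiment 1 those of B cell (0.0786) and proliferation genes (0.0195). Leaving out 1 library at a time gave 0.0856 to 0.112 for enteric nervous, -0.0139 to 0.0604 for fibroblast, -0.181 to -0.138 for goblet, -0.0138 to 0.0153 for proliferation and -0.192 to -0.182 for smooth-muscle genes. The FFPE difference ran from -6.25 to 4.25 in thinned genes per spot and from -6093 to -4428 in UMIs per spot. The difference between experiments ran from 21.67 to 36.5 in thinned genes per spot and from -0.951 to 0.527 in the percentage of mucosal spots.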

Other observations

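The correlations over spots and Moran's I in the human sections were planned, and no test was chosen after seeing the data.

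Correlations between gene programmes over the spots of the human pancreatic sections differed between the 3 donors. T cell and MHC class II genes had partial correlations over spots of 0.607, 0.181 and 0.220 in donors A, B and C, and hypoxia and neutrophil genes of 0.617, 0.0802 and 0.0727. Hypoxia and proliferation genes, which ran against each other in all 8 mice, had positive correlations of 0.458, 0.201 and 0.0357. Fibroblast and proliferation genes had 0.348, 0.203 and -0.353, and fibroblast and macrophage genes 0.358, 0.215 and 0.106. The lists are shares of all UMIs of a spot, and acinar genes took 12.4% of UMIs in donor A, with a Moran's I of 0.896. Whether this moved the correlations of other lists there was not tested. Median UMIs per spot were 30740 in donor A, 2281.5 in donor B and 2239 in donor C, and the difference between donors or from the mice was not tested.

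Moran's I of the tumour programmes differed between the donors. Moran's I of the classical programme was 0.647, 0.622 and 0.310 in donors A, B and C, and that of the basal-like programme 0.115, 0.526 and 0.103. In the same order the classical list stood at 6263, 7111 and 1711 CPM and the basal-like list at 213, 1250 and 323. Spots were thinned to equal totals first, so a scarce list left few UMIs per spot, which limits its Moran's I. For these 2 lists the values therefore cannot separate a difference in spatial pattern from a difference in level. Myofibroblast genes, a stromal list, had 0.405, 0.707 and 0.584. LYZ, the lysozyme gene, had the most UMIs of the classical list in each donor, at 1815, 2529 and 525 CPM in the same order.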
